A study of Rattus norvegicus with 18 samples.

How the data were processed

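Messenger RNA was measured in cultured neonatal rat ventricular cardiomyocytes, in 18 libraries that form 6 groups of 3. The groups were Vehicle, phenylephrine (PE), PE with Senexin A at 10 µM or 50 µM, and Senexin A alone at the same doses. Groups and replicate numbers were taken from the labels.

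The deposited table held 1 FPKM column per library (fragments scaled by gene length and by mapped fragments), and per the labels the RNA was selected for polyadenylated tails before sequencing. Bowtie2, Cufflinks and the rn5 build were used, per the submitters' processing notes, but the versions, the annotation and any filter were not given in the sources used here. The table had 17303 rows, and its smallest value was a floor of 0.01 FPKM. Of these, 2766 rows stood at the floor in all libraries, and 27.4% of values stood there. Whether reads were assigned by strand was not stated, and 1875 rows shared their locus with another row (1000 of those tested), so their values are uncertain. Gene symbols were used as the table gives them; 14801 matched a reference symbol and 16914 matched a symbol or a synonym.

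The FPKM sums ran from 610324 to 910958 per library. Total reads were not given, but rows under 0.2 FPKM fell on steps that let libraries be compared: in each of the other libraries 567 to 709 such rows were compared with Vehicle replicate 2, the reference, 125 to 208 lay at the most frequent step, and the relative depth ran from 0.906 to 1.206. Absolute depth stays unknown, so no counting interval was given. Libraries of the same group correlated across genes with r from 0.9863 to 0.9923, and no pair of them held more than 2 equal values above the floor.

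Values were tested as log2(FPKM + 1) with limma 3.58.1 (moderated statistics with a trend of variance on mean level) in R 4.3.3. Rows with at least 1 FPKM in at least 3 libraries entered, which left 10478. All 6 group means were fitted in 1 model, with 12 residual degrees of freedom, and p-values were adjusted per comparison by the Benjamini-Hochberg method, with genes called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their standard error (SE). The median SE was 0.118, and 0.167 for the differences between responses. Group levels are given as mean ± SD of 3 libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

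PE was compared with Vehicle, each dose with its own background (with PE, or without), PE with no PE at each dose, and 50 µM with 10 µM. The difference between the PE responses with and without the inhibitor was tested as an interaction. Before the data were examined, 36 lists of 627 genes were fixed (pathways, complexes and cell types), and 34 of them had at least 3 tested members. A list was compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes, and adjusted over the 34 lists of a comparison. The same test with an estimated correlation was an alternative. fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, was also run. Of 374 list results, 119 passed camera with the preset correlation and 1 passed with the estimated one. List counts were not repeated with single libraries left out.

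The genes named were set by a rule. It took the 6 largest rises and the 6 largest falls of each comparison, among called genes with a mean of at least 5 FPKM in a compared group and with groups that did not overlap (chance gives 10% of genes such groups at 3 against 3). It also took up to 4 called members of each list described, and a fixed panel (Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Ankrd1, Cdk8, Cdk19, Ccnc, Med12 and Med13). For interactions the groups could overlap. Entries without a gene symbol were passed over. Myh6 and Myh7 are near-identical paralogs whose reads the counting could have split, so their values are uncertain.

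Replicate numbers paired the libraries. Deviations from group means correlated by 0.213 to 0.587 (median 0.435) in all 45 pairs with the same number and by -0.462 to 0.095 in pairs with different numbers, and in 90 of 90 tests the best match of a library in another group had its own number. The source of the pairing is not in the labels. The model was kept without a block, as planned, and a fit with the replicate block was an alternative. The labels do not say that replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical in part.

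Alternatives were a pseudocount of 0.1 or 0.5, no filter, a filter of 5 FPKM, quantile normalization, median-ratio scaling, a fit of the compared groups only, the replicate block, no variance trend, array weights, a minimum log2 fold change of 1, and leaving out each library. The replicate block together with an estimated correlation was added for the lists after seeing the data. Overlaps between comparisons that share libraries were set against 100 simulated draws with no effect and against the overlap of independent lists. Other splits of the samples were counted too. For the interactions 100 splits were drawn, unique by the sign each library takes; this draw replaced an earlier one, unique by group labels, that gave the same verdicts.

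The gene test was tested on simulated data with 200 changed genes, 50 of each size. For PE against Vehicle it recovered 68%, 88%, 100% and 98% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 12 false calls among 189. For 50 µM with PE it recovered 62%, 96%, 100% and 98%, with 7 false among 185. For the interaction at 50 µM it recovered 24%, 74%, 100% and 100%, with 8 false among 157. The simulated noise was independent between libraries, without the pairing by replicate number. The changed genes had a mean above 1 on the log2 scale and changed in 1 group only. Far fewer genes changed than were called in most real comparisons, so recovery and false calls may differ in these data. No sample was left out.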

Results

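RNA from cultured heart muscle cells of newborn rats (ventricle, Wistar, day 3 after birth) was sequenced in 18 libraries, 3 in each of 6 groups. PE, an agonist of alpha1-adrenergic receptors that drives hypertrophic growth in such cultures, was given at 10 µM for 48 h. Senexin A, an inhibitor of the kinase CDK8 of the Mediator complex, was given at 10 or 50 µM, with PE or alone. Before treatment, all cultures had 48 h of AraC, a drug that kills dividing cells, and 24 h without serum. FPKM sums were 610324 to 660958 in Vehicle, 810428 to 853958 in PE, and up to 910958 in the groups with inhibitor. The 10 most abundant genes took 9.64% to 12.37% of the sum in Vehicle and 19.24% to 20.72% in PE, led in each library by Myl2, the ventricular regulatory myosin light chain. With PE they took 17.87% to 18.64% at 10 µM and 13.71% to 15.07% at 50 µM; without PE they took 11.95% to 14.55% and 11.12% to 13.12%. The first components of the gene levels held 48.1% and 21.2% of the variance.

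The transcripts of the drug's targets were measured first. Cdk8 stood at 13.5 ± 0.919 FPKM in Vehicle, 13.0 ± 1.65 in PE, 15.6 ± 0.917 in PE with 10 µM and 16.0 ± 2.59 in PE with 50 µM (mean ± SD, n = 3). Its PE effect was -0.06 ± 0.11 on the log2 scale (limma, adjusted p = 0.72), and its effects of 10 and 50 µM without PE were -0.02 (adjusted p = 0.92) and -0.07 (adjusted p = 0.61). Ccnc, the cyclin partner of CDK8, rose at 50 µM without PE by 0.32 (adjusted p = 0.0057). Cdk19 of the panel changed by -0.37 ± 0.17 with PE (limma adjusted p = 0.11). That passed with the replicate block (0.0164), in the compared groups only (0.0439) and with array weights (0.0479). At 50 µM without PE Cdk19 changed by -0.37 (adjusted p = 0.071). That passed with the block (0.00998), with array weights (0.0354) and without 50 µM replicate 1 (0.0284). At 50 µM with PE it was -0.17 (adjusted p = 0.42). Among the 6 tested genes of the Mediator kinase module, which holds CDK8 and its partners, 1 fell with PE, 2 rose at 50 µM with PE, and 1 rose and 1 fell at 50 µM without PE. Camera gave adjusted p = 0.57 for PE and 0.64 for 50 µM with PE. Med12 fell with PE (-0.25 ± 0.081, adjusted p = 0.03), a call lost after quantile normalization (0.0821), in the compared groups only (0.0825), without Vehicle replicates 1 and 3 (0.0709 and 0.137) and without PE replicates 1, 2 and 3 (0.0655, 0.0827 and 0.0595). Cdk8 rose at 50 µM with PE by 0.28 (adjusted p = 0.045), a call lost with no filter (0.0636), with median-ratio scaling (0.0529) and in the compared groups only (0.126). It was also lost without PE replicates 1 and 2 (0.0725 and 0.208) and without PE with 50 µM replicates 1 and 2 (0.158 and 0.184). Ccnc rose there by 0.29 (adjusted p = 0.012), a call lost without PE replicate 1 (0.0569) and without PE with 50 µM replicate 2 (0.0649). Med13 fell at 50 µM without PE (-0.32, adjusted p = 0.019), a call lost after quantile normalization (0.153), in the compared groups only (0.0566), without Vehicle replicate 3 (0.0749) and without 50 µM replicates 1 and 2 (0.0818 and 0.0726).

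PE was compared with Vehicle to see what the hypertrophic stimulus changed. Acta1, the skeletal alpha-actin of fetal and overloaded hearts, rose from 181 ± 33.8 to 3078 ± 287 FPKM (log2 fold change 4.09 ± 0.18 SE, limma adjusted p = 1.1e-09). Nppb, which encodes brain natriuretic peptide, rose from 562 ± 325 to 5221 ± 275 FPKM (3.37 ± 0.33, adjusted p = 2.1e-06). Nppa, which encodes atrial natriuretic peptide, rose from 5101 ± 3958 to 28570 ± 3051 FPKM (2.84 ± 0.45, adjusted p = 0.00025). Xirp2, an actin-binding protein of the intercalated disc, rose by 3.01 ± 0.26 (adjusted p = 7.9e-07) and Tceal7 by 3.46 ± 0.3 (adjusted p = 7.2e-07). Ankrd1, a stretch-responsive protein of the sarcomere, rose by 1.69 ± 0.17 (adjusted p = 4.1e-06). Igfbp3, which binds insulin-like growth factors, fell by 2.02 ± 0.14 (adjusted p = 9.3e-08) and Angptl4, an inhibitor of lipoprotein lipase, fell by 1.86 ± 0.22 (adjusted p = 1.5e-05). In rn5, Acta1 lies on chromosome 19 from 67389898 to 67392911, Nppb on chromosome 5 from 168454330 to 168455633, and Nppa on chromosome 5 from 168466308 to 168467618.

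The gene lists fixed before the data were seen were then tested for PE. In what follows, the count adjusted over the list alone is given where it differs from the count over all genes. Of 15 genes of the fetal and hypertrophic programme 10 rose and 1 fell (11 and 2 adjusted over the list alone; median 1.59, camera adjusted p = 1.1e-07, adjusted p = 0.40 with an estimated correlation), and fry gave an adjusted p of 8.9e-07 for a rise on balance. Of 19 sarcomere genes 17 rose (median 0.95, adjusted p = 2.7e-10, adjusted p = 0.47 with an estimated correlation). Among them were Csrp3, a Z-disc protein (2.13 ± 0.20, adjusted p = 1.5e-06), and Myl3, a ventricular myosin light chain (1.65 ± 0.14, adjusted p = 5.6e-07). After quantile normalization 11 of the 19 rose and 2 fell, and the medians were lower in several lists: 0.36 for the sarcomere, 1.03 for the fetal programme, 0.28 for oxidative phosphorylation (20 higher, 1 lower) and 0.34 for the tricarboxylic acid cycle. Of 29 genes of oxidative phosphorylation 24 rose and 1 fell (26 and 1 adjusted over the list alone; median 0.62, adjusted p = 1.4e-10, adjusted p = 0.74 with an estimated correlation). Of 15 genes of the tricarboxylic acid cycle 14 rose (adjusted p = 7.9e-09, adjusted p = 0.48 with an estimated correlation). The pyruvate dehydrogenase subunit Pdha1 rose by 1.31 ± 0.12 (adjusted p = 1.2e-06). Of 20 glycolysis genes 13 rose and 1 fell (adjusted p = 8.6e-06, adjusted p = 0.48 with an estimated correlation), led by the muscle enolase Eno3 (2.58 ± 0.17, adjusted p = 8.1e-08). Of 24 genes of sterol and fatty acid synthesis 22 rose (23 adjusted over the list alone; median 1.32, adjusted p = 1.8e-15, adjusted p = 0.48 with an estimated correlation). Among them was Fdps, an enzyme of cholesterol synthesis (2.23 ± 0.18, adjusted p = 4.1e-07).

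Other lists were tested in the same comparison. Of 30 cell cycle genes 18 rose and 2 fell (median 0.57, adjusted p = 0.00056, adjusted p = 0.74 with an estimated correlation), including the mitotic cyclin Ccnb1 (1.25 ± 0.18, adjusted p = 9.4e-05). Of 25 immediate early genes 10 rose (adjusted p = 0.014, adjusted p = 0.74 with an estimated correlation). Dusp4, a phosphatase of MAP kinases, rose by 2.17 ± 0.21 (adjusted p = 2.7e-06). Of 15 heat shock genes 8 rose (9 adjusted over the list alone; adjusted p = 0.00027, adjusted p = 0.40 with an estimated correlation, and 0.07 after quantile normalization, with 4 higher and 1 lower). Hspb7 rose by 1.24 ± 0.12 (adjusted p = 1.8e-06). Of 22 genes of the unfolded protein and integrated stress response 1 rose and 9 fell (median -0.32, adjusted p = 0.029, adjusted p = 0.74 with an estimated correlation). Among them were the cystine transporter Slc7a11 (-0.69 ± 0.15, adjusted p = 0.0023). Of 28 genes of fatty acid oxidation 7 rose and 5 fell (median 0.14, and -0.08 with 7 higher and 10 lower after quantile normalization; adjusted p = 0.82), and of 16 genes of calcium handling 6 rose and 2 fell (adjusted p = 0.14). Of 20 extracellular matrix genes 3 fell, 11 with the replicate block and 11 after quantile normalization, with a median of -0.61 (0 adjusted over the list alone; median -0.33, adjusted p = 0.037, adjusted p = 0.74 with an estimated correlation). Of 11 fibroblast markers, which measure other cells in the culture, 1 fell, 6 with the replicate block (median -0.39, adjusted p = 0.14, 0.016 with the replicate block, and 0.64 with the block and an estimated correlation, chosen after seeing the data).

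In limma's test 3205 genes passed for PE against Vehicle, 1874 higher and 1331 lower, and 334 of them changed at least 2-fold (260 higher, 74 lower). After quantile normalization the share of higher genes was 47.7% in place of 58.5%.

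**Figure D1:**
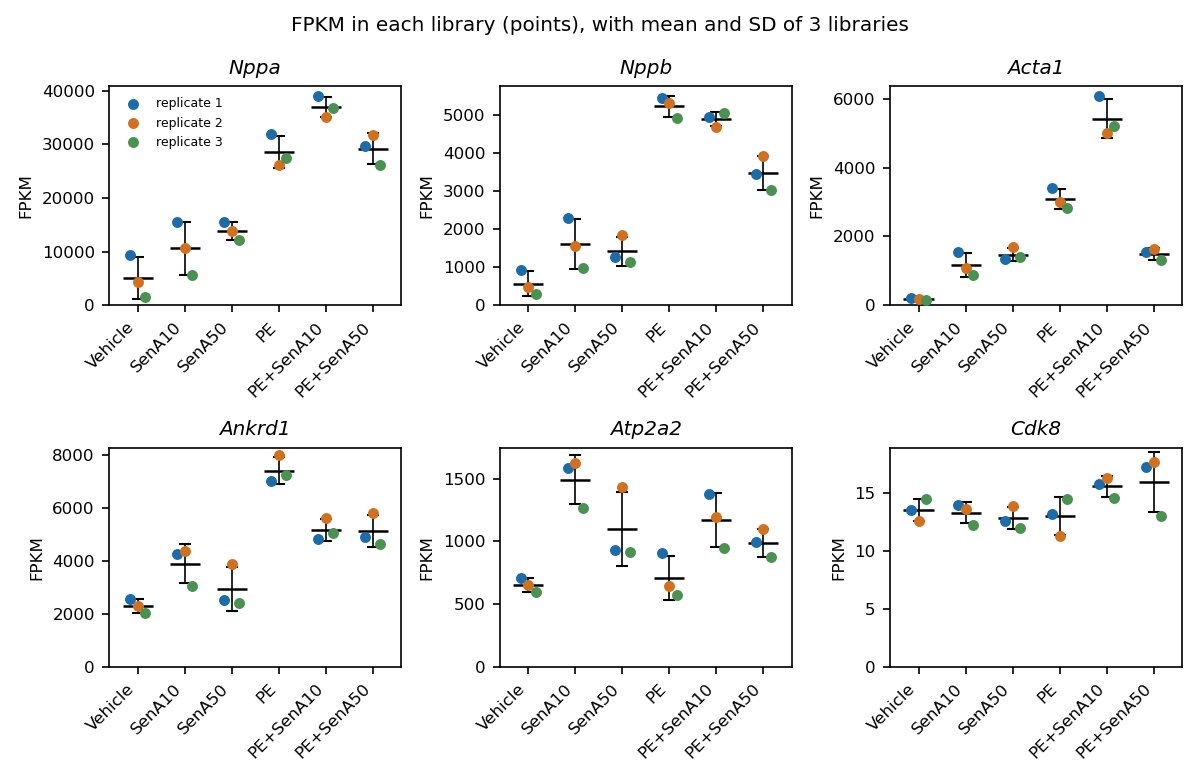
FPKM (linear axes from 0) of 6 genes in each library of the 6 groups; points are libraries marked by replicate number, with the mean and SD of 3. Acta1 stands at 181 in Vehicle and 3078 in PE, and Cdk8 between 12.9 and 16.0 in each group mean.

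The lower dose was added to PE to see which levels in PE it changed. Klf2, a transcription factor known from endothelial flow responses, fell from 20.5 ± 5.48 to 4.67 ± 1.72 FPKM (-1.93 ± 0.29, adjusted p = 0.0005). Xirp2 fell from 232 ± 32.1 to 55.1 ± 5.94 FPKM (-2.05 ± 0.26, adjusted p = 0.00015) and Adamts19, a secreted metalloprotease, fell by 1.86 ± 0.13 (adjusted p = 3.5e-07). Acta1 rose to 5426 ± 570 FPKM (0.82 ± 0.18, adjusted p = 0.0055), while Nppb (-0.1, adjusted p = 0.87) and Nppa (0.38, adjusted p = 0.61) did not pass. Ankrd1 changed by -0.52 ± 0.17 (limma adjusted p = 0.051). It passed in several alternatives, among them the replicate block (0.00558) and quantile normalization (0.0304). Atp2a2, the calcium pump SERCA2, rose by 0.74 ± 0.19 (limma adjusted p = 0.016). That call was lost without PE replicates 2 and 3 (0.0593 and 0.0815) and without PE with 10 µM replicate 1 (0.0781). Slc2a1, the glucose transporter GLUT1, rose from 23.6 ± 2.73 to 91.8 ± 12.2 FPKM (1.92 ± 0.12, adjusted p = 3.5e-07), and Ntsr2, a neurotensin receptor, by 2.77 ± 0.19 (adjusted p = 3.5e-07).

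The lists were tested at 10 µM with PE as well. Of 28 genes of fatty acid oxidation 12 rose, and with the replicate block 20 rose and 1 fell (14 rose adjusted over the list alone; median 0.30, adjusted p = 2.8e-05, adjusted p = 0.85 with an estimated correlation). Plin5, a lipid droplet coat protein, rose by 1.21 ± 0.17 (adjusted p = 0.0003). Of 20 glycolysis genes 12 rose (adjusted p = 1.8e-05, adjusted p = 0.85 with an estimated correlation). Of 29 genes of oxidative phosphorylation 6 rose, 14 with the replicate block (6 adjusted over the list alone; adjusted p = 0.00061, adjusted p = 0.85 with an estimated correlation). Of 15 genes of the tricarboxylic acid cycle 3 rose (adjusted p = 0.058, 0.03 with the replicate block, and 0.77 with the block and an estimated correlation). Of 25 immediate early genes 1 rose and 7 fell, 1 and 12 with the replicate block (1 and 9 adjusted over the list alone; median -0.43, adjusted p = 0.00034, adjusted p = 0.85 with an estimated correlation). Among them were Jund, an AP-1 subunit (-0.92 ± 0.11, adjusted p = 0.00011), and Atf3, a stress-induced repressor (-1.02 ± 0.23, adjusted p = 0.0063). Of 20 extracellular matrix genes 3 fell, and with the replicate block 11 fell and 2 rose (3 adjusted over the list alone; median -0.36, adjusted p = 0.011, adjusted p = 0.85 with an estimated correlation), beside 2 of 11 fibroblast markers, 4 with the replicate block (median -0.24). Of 8 macrophage markers 0 rose, 4 with the replicate block (median 0.55, adjusted p = 0.44). The fetal and hypertrophic genes (2 higher, 3 lower of 15, 6 lower with the replicate block, adjusted p = 0.26) and the sarcomere genes (3 higher, 4 lower of 19, adjusted p = 0.48) went both ways; the Z-disc gene Csrp3 fell (-1.04 ± 0.20, adjusted p = 0.0022).

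In limma's test 1778 genes passed at 10 µM with PE, 957 higher and 821 lower, and 129 changed at least 2-fold (78 higher, 51 lower). The count was 1140 without PE replicate 2, 1042 without PE replicate 3, 1100 without PE with 10 µM replicate 1, and 2924 with the replicate block.

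The higher dose was added to PE in the same way. Acta1 fell to 1490 ± 163 FPKM (-1.05 ± 0.18, adjusted p = 0.00011) and Xirp2 to 25.01 ± 3.76 FPKM (-3.16 ± 0.26, adjusted p = 9.3e-08). Tceal7 fell by 3.75 ± 0.3 (adjusted p = 5.8e-08). Nppb (-0.6 ± 0.33, adjusted p = 0.13, and 0.00878 in a fit of the compared groups only) and Nppa (0.03, adjusted p = 0.96) did not pass. Ankrd1 changed by -0.54 ± 0.17 (limma adjusted p = 0.015). That call was lost without PE replicate 2 (0.0557) and without PE with 50 µM replicate 3 (0.058). Atp2a2 rose by 0.5 ± 0.19 (limma adjusted p = 0.035), a call lost with no filter (0.0588) and in several omissions of 1 library. Gstk1, a mitochondrial and peroxisomal glutathione transferase, rose from 13.2 ± 2.22 to 261.6 ± 54.8 FPKM (4.2 ± 0.19, adjusted p = 4.3e-10). B3gat1, a glucuronyltransferase, rose by 5.32 ± 0.37 (adjusted p = 1.9e-08), and Slc2a1 by 2.45 ± 0.12 (adjusted p = 9.3e-10). Myh7, the slow myosin heavy chain, fell by 4.56 ± 0.5 (adjusted p = 1.4e-06), a value that is uncertain because Myh6 is nearly identical. Myh7 fell alike at 50 µM without PE (-4.11 ± 0.5, adjusted p = 3.3e-06), and its interaction at 50 µM did not pass (-0.45, adjusted p = 0.77). With PE alone Myh7 rose by 1.59 ± 0.5 (adjusted p = 0.024), a call lost after quantile normalization (0.101) and in several omissions of 1 library. Myh6, equally uncertain, rose at 10 and 50 µM by 2.39 and 1.87 with PE. Without PE it rose by 2.46 and 1.96 (adjusted p from 0.021 to 0.03 in these 4), calls also lost in several omissions.

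Each of the 30 cell cycle genes fell at 50 µM with PE (30 adjusted over the list alone; median -1.48, adjusted p = 3.6e-16, adjusted p = 0.53 with an estimated correlation). Among them were Mcm6, a replication helicase subunit (33.7 ± 4.52 to 7.25 ± 1.15 FPKM, -2.08 ± 0.16, adjusted p = 4.9e-08), and the mitotic regulator Cdc20 (-2.06 ± 0.18, adjusted p = 1.9e-07). Of 22 genes of the unfolded protein and integrated stress response 19 rose and 2 fell (19 and 3 adjusted over the list alone; median 1.80, adjusted p = 6.5e-07, adjusted p = 0.53 with an estimated correlation). Asns, asparagine synthetase, rose from 29.97 ± 7.1 to 233.6 ± 7.84 FPKM (2.95 ± 0.23, adjusted p = 4.3e-08) and Trib3, a pseudokinase induced by ATF4 and CHOP, by 3.26 ± 0.41 (adjusted p = 6.7e-06). Of 20 genes of ribosome biogenesis 16 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 1.9e-05, adjusted p = 0.14 with an estimated correlation). Gnl3, nucleostemin, rose by 0.91 ± 0.08 (adjusted p = 1.3e-07). Of 19 sarcomere genes 1 rose and 13 fell (median -0.90, adjusted p = 0.00022, adjusted p = 0.53 with an estimated correlation). Among them were Csrp3 (-2.21 ± 0.20, adjusted p = 1.7e-07) and the thick filament protein Mybpc3 (-1.38 ± 0.11, adjusted p = 4.9e-08). Of 16 genes of calcium handling 4 rose and 9 fell (adjusted p = 0.021, adjusted p = 0.53 with an estimated correlation). Hrc and Trdn, proteins of the calcium store, fell by 1.98 ± 0.15 (adjusted p = 3.1e-08) and 1.45 ± 0.12 (adjusted p = 1e-07). Of 15 fetal and hypertrophic genes 1 rose and 8 fell (median -0.60, adjusted p = 0.019, adjusted p = 0.53 with an estimated correlation).

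Matrix genes and TGF-beta and BMP targets fell in the same comparison. Of 20 extracellular matrix genes 15 fell (median -0.89, adjusted p = 0.001, adjusted p = 0.53 with an estimated correlation). Osteonectin, Sparc, fell by 1.36 ± 0.11 (adjusted p = 7.7e-08) and fibronectin, Fn1, fell by 1.4 ± 0.21 (adjusted p = 3.2e-05). Of 15 TGF-beta and BMP targets 2 rose and 10 fell (2 and 11 adjusted over the list alone; adjusted p = 0.026, adjusted p = 0.54 with an estimated correlation). Tgfbi fell by 1.99 ± 0.16 (adjusted p = 7.5e-08). Markers of other cells stood beside them: 4 of 11 fibroblast markers fell (median -0.39, adjusted p = 0.18; Pcolce -1.83 ± 0.17, adjusted p = 2.2e-07), and 3 of 6 endothelial markers fell (median -0.50; Flt1 -1.04 ± 0.17). Also, 3 of 11 smooth muscle markers fell, 6 with the replicate block (median -0.35; Acta2 -1.52 ± 0.18, adjusted p = 3.1e-06), while the median of 8 macrophage markers was 0.46 (2 higher with the replicate block). Of 25 immediate early genes 2 rose and 13 fell (median -0.34, adjusted p = 0.016, adjusted p = 0.53 with an estimated correlation). Dusp1 fell by 1.39 ± 0.14 (adjusted p = 6.2e-07) and Myc rose by 1.63 ± 0.30 (adjusted p = 0.00026). Of 29 genes of oxidative phosphorylation 7 rose and 6 fell, 12 and 7 with the replicate block (median 0.10, and 0.01 after quantile normalization; adjusted p = 0.61).

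In limma's test 5939 genes passed at 50 µM with PE, 3065 higher and 2874 lower, and 1084 changed at least 2-fold (433 higher, 651 lower). The same PE libraries enter this comparison and that of PE with Vehicle, so part of any excess overlap between them may come from those libraries, which are too few to split.

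The genes called for PE were compared with those called for the inhibitor in PE. Of the genes that rose with PE, 703 fell at 50 µM with PE (514 expected of independent lists) and 215 fell at 10 µM (146.8). Of the genes that fell with PE, 414 rose at 50 µM (389.3) and 132 rose at 10 µM (121.6). In the same direction, 284 rose with PE and again at 10 µM (171.2), and 138 fell in both (104.3). At 50 µM 498 rose in both (548.2) and 387 fell in both (365.1). Against Vehicle, 50 µM alone raised 942 of the genes that rose with PE (570.9) and lowered 423 (566.8). It lowered 678 of those that fell (402.6) and raised 219 (405.5). At 10 µM alone these counts were 453 (171.9), 83 (131.5), 180 (93.4) and 72 (122.1), with the Vehicle libraries shared. Draws with no effect gave 0 in each, but hardly any gene is called there, so they say little about these overlaps. The fold changes of PE and of 50 µM with PE had a covariance of -0.0373, against -0.0152 simulated from the shared libraries; for 10 µM it was 0.000751 against -0.0152. The simulated draws did not include the pairing by replicate number. Without Vehicle replicate 3 the 414 became 272, without PE replicates 2 and 3 the 215 became 137 and 129, and without PE replicate 2 the 132 became 84. With the replicate block the counts of 215, 132 and 414 became 350, 264 and 629.

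Senexin A alone was compared with Vehicle to see what it did without the stimulus. At 10 µM, Acta1 rose to 1169 ± 346 FPKM from 181 ± 33.8 (2.66 ± 0.18, adjusted p = 4.1e-07), and Atp2a2, the calcium pump SERCA2, from 652 ± 57.8 to 1494 ± 197.6 FPKM (1.19 ± 0.19, adjusted p = 0.0007). Fbxl22, an F-box protein of the sarcomere, rose by 2.46 ± 0.15, and Trim50, a ubiquitin ligase, by 2.53 ± 0.2 (adjusted p = 2.4e-06). Ankrd1 rose by 0.75 ± 0.17 (adjusted p = 0.0091) and Nppb by 1.59 ± 0.33 (adjusted p = 0.0038, and 0.0522 in a fit of the compared groups only). Nppa (1.29) did not pass at an adjusted p of 0.063, though it did without Vehicle replicate 1 (0.00547), without 10 µM replicate 3 (0.0263) and with the replicate block (0.0129). Klf2 fell from 30.1 ± 6.3 to 9.45 ± 1.84 FPKM (-1.57 ± 0.29, adjusted p = 0.0021).

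The lists were tested at 10 µM without PE in turn. Of 29 genes of oxidative phosphorylation 26 rose (29 adjusted over the list alone; median 0.57, adjusted p = 3.9e-17, adjusted p = 0.41 with an estimated correlation). Cytochrome c, Cycs, rose by 0.94 ± 0.18 (adjusted p = 0.0023). Of 28 genes of fatty acid oxidation 17 rose (20 adjusted over the list alone; adjusted p = 4e-09, adjusted p = 0.37 with an estimated correlation). Plin5 rose by 1.43 ± 0.17 (adjusted p = 6e-05) and the carnitine transferase Cpt1b by 0.79 ± 0.13 (adjusted p = 0.00078). Of 15 genes of the tricarboxylic acid cycle 10 rose (12 adjusted over the list alone; adjusted p = 2.6e-07, adjusted p = 0.48 with an estimated correlation). Of 19 sarcomere genes 12 rose (median 0.56, adjusted p = 1.2e-07, adjusted p = 0.41 with an estimated correlation). Actc1, cardiac alpha-actin, rose by 1.26 ± 0.14 (adjusted p = 5e-05). Of 15 fetal and hypertrophic genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.59, adjusted p = 0.001, adjusted p = 0.41 with an estimated correlation). Rcan1, a calcineurin regulator, rose by 1.08 ± 0.14 (adjusted p = 0.00015). Of 14 nuclear receptors and coactivators of mitochondrial genes 5 rose (adjusted p = 0.0041, adjusted p = 0.37 with an estimated correlation), including Ppargc1a (1.06 ± 0.22, adjusted p = 0.0038) and Ppara (1.00 ± 0.13, adjusted p = 0.00016). Of 30 cell cycle genes 13 fell (15 adjusted over the list alone; median -0.32, adjusted p = 6e-07, adjusted p = 0.54 with an estimated correlation). Mcm5 fell by 0.65 ± 0.14 (adjusted p = 0.0061). Of 20 extracellular matrix genes 1 fell, and 3 fell after quantile normalization (median -0.17, and -0.28 after it; adjusted p = 0.27). The quantile medians of oxidative phosphorylation and of the sarcomere were 0.36 and 0.34. Among markers of other cells, 1 of 11 for fibroblasts fell (median 0.01, adjusted p = 0.9). Of 8 for macrophages 0 rose, 4 with the replicate block (median 0.53, adjusted p = 0.36, 0.03 with the replicate block, and 0.61 with the block and an estimated correlation).

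In limma's test 1696 genes passed at 10 µM without PE, 961 higher and 735 lower, and 125 changed at least 2-fold (102 higher, 23 lower). The count was 1005 without Vehicle replicate 3, 948 without 10 µM replicate 2, and 2761 with the replicate block.

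The higher dose was given without PE in the same way. Acot2, a mitochondrial acyl-CoA thioesterase, rose at 50 µM from 16.9 ± 4.13 to 341.7 ± 37.4 FPKM (4.28 ± 0.17, adjusted p = 1e-10). Acta1 rose to 1470 ± 186 FPKM (3.02 ± 0.18, adjusted p = 2.9e-09), and Nppb and Nppa rose by 1.46 ± 0.33 (adjusted p = 0.0011) and 1.79 ± 0.45 (adjusted p = 0.0028). Atp2a2 rose by 0.72 ± 0.19 (limma adjusted p = 0.0041, and 0.102 after quantile normalization). Ankrd1 (0.32 ± 0.17, limma adjusted p = 0.12) did not pass, though it did with the replicate block (0.0303). Ptgfr, the receptor of prostaglandin F2-alpha, fell from 157 ± 12.8 to 12.1 ± 3.01 FPKM (-3.62 ± 0.19, adjusted p = 1.1e-09). Each of the 30 cell cycle genes fell (30 adjusted over the list alone; median -1.88, adjusted p = 6.3e-17, adjusted p = 0.40 with an estimated correlation). Mcm6 fell by 2.72 ± 0.16 (adjusted p = 3e-09). Of 22 genes of the unfolded protein and integrated stress response 18 rose and 3 fell (median 1.63, adjusted p = 1.9e-05, adjusted p = 0.54 with an estimated correlation). Among them were Trib3 (3.15 ± 0.41, adjusted p = 8e-06) and the stress hormone gene Fgf21 (3.03 ± 0.19, adjusted p = 4e-09).

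Other lists were tested at this dose without PE. Of 29 genes of oxidative phosphorylation 27 rose, and after quantile normalization 21 rose and 1 fell, with a median of 0.40 (median 0.76, adjusted p = 1.6e-07, adjusted p = 0.54 with an estimated correlation). Cox6a2, the heart isoform of a cytochrome oxidase subunit, rose by 1.41 ± 0.17 (adjusted p = 2.5e-06). Of 28 genes of fatty acid oxidation 19 rose and 4 fell (19 and 5 adjusted over the list alone; adjusted p = 0.00075, adjusted p = 0.54 with an estimated correlation). Ucp3 rose by 2.17 ± 0.17 (adjusted p = 3.1e-08). Of 20 glycolysis genes 14 rose and 2 fell (adjusted p = 0.0015, adjusted p = 0.54 with an estimated correlation). Of 20 ribosome biogenesis genes 16 rose and 1 fell (adjusted p = 0.00014, adjusted p = 0.28 with an estimated correlation). Rrp9 rose by 1.05 ± 0.06 (adjusted p = 2.7e-09). Of 20 extracellular matrix genes 15 fell (median -1.12, adjusted p = 0.00022, adjusted p = 0.54 with an estimated correlation), with Fn1 at -1.51 ± 0.21 (adjusted p = 1.3e-05). Of 15 TGF-beta and BMP targets 1 rose and 10 fell (1 and 12 adjusted over the list alone; adjusted p = 0.0091, adjusted p = 0.54 with an estimated correlation). Beside them 5 of 11 fibroblast markers fell, 8 with the replicate block (median -0.64, and -0.38 after quantile normalization; adjusted p = 0.074, 0.024 with the replicate block, and 0.48 with the block and an estimated correlation, chosen after seeing the data). So did 4 of 11 smooth muscle markers (median -0.56, adjusted p = 0.11, 0.035 with the replicate block, and 0.44 with both) and 2 of 6 endothelial markers (median -0.29, and -0.17 after quantile normalization), while the median of 8 macrophage markers was 0.00. The sarcomere genes went both ways (6 higher, 7 lower of 19; median -0.17, adjusted p = 0.57, and 0.049 after quantile normalization, with a median of -0.37).

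In limma's test 6361 genes passed at 50 µM without PE, 3192 higher and 3169 lower, and 1281 changed at least 2-fold (534 higher, 747 lower). The effects with and without PE share no library. At 50 µM, 2388 genes were higher and 2303 lower in both backgrounds (933.7 and 869.2 expected of independent lists), and the fold changes correlated across genes with r = 0.846. At 10 µM, 480 were higher and 349 lower in both (87.8 and 57.6 expected), with r = 0.672. Genes are not independent replicates.

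**Figure D2:**
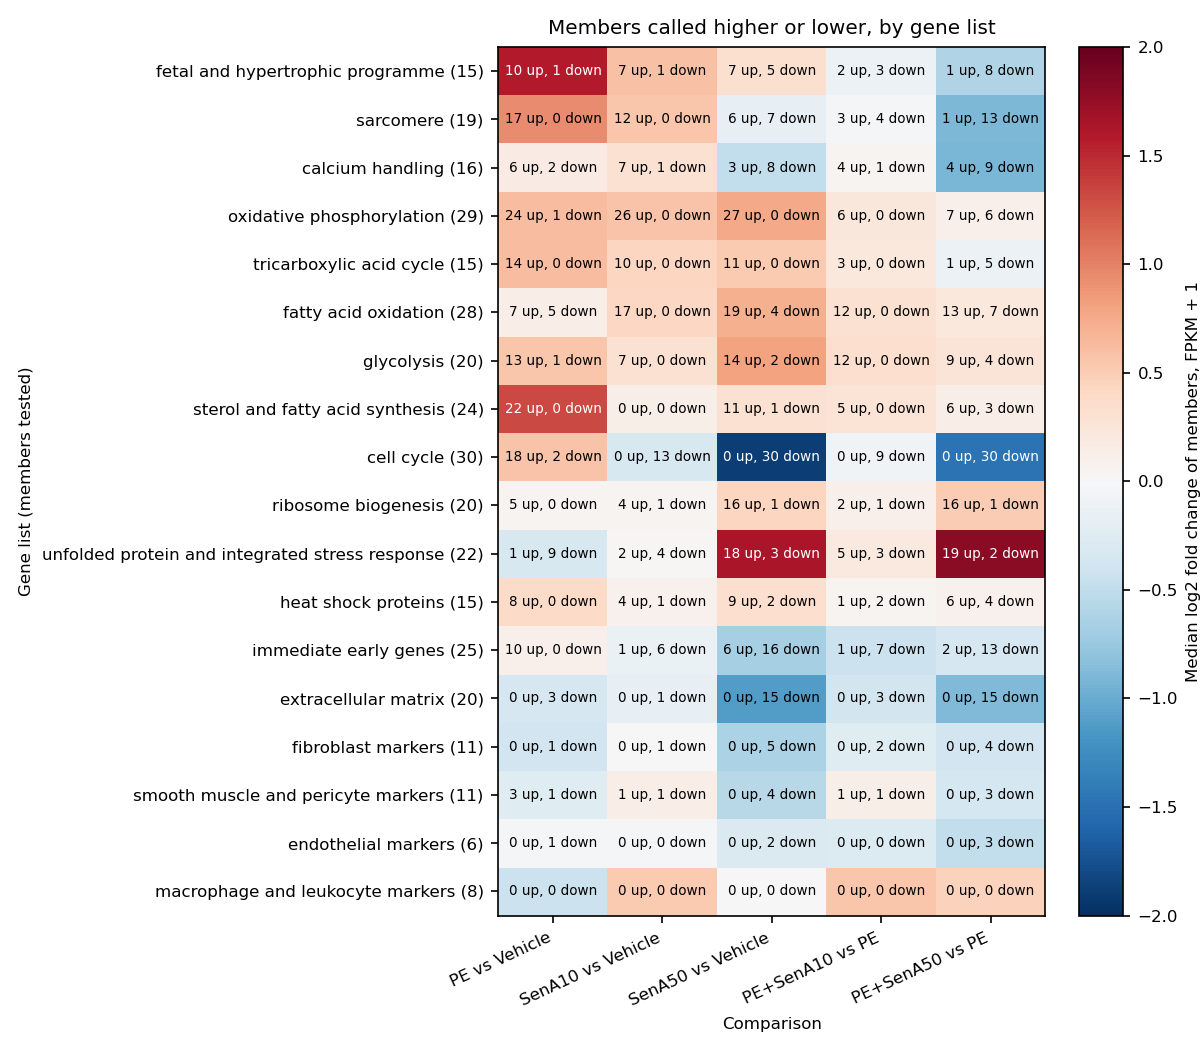
Heat map of 18 gene lists in 5 comparisons; colour gives the median log2 fold change of the list's tested members (scale from -2 to 2) and the text gives the members called higher and lower. Cell cycle genes are lower at 50 µM in both backgrounds, with medians of -1.48 with PE and -1.88 without.

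The doses were compared directly to see where 50 µM differed from 10 µM. With PE, Acta1 was lower at the higher dose (-1.86, adjusted p = 8.6e-07). So were 29 of 30 cell cycle genes (30 adjusted over the list alone; median -1.48, adjusted p = 4.5e-20, adjusted p = 0.27 with an estimated correlation) and 13 of 19 sarcomere genes (median -0.74, adjusted p = 2.5e-06, adjusted p = 0.51 with an estimated correlation). Of 16 genes of calcium handling 10 were lower (median -0.67, adjusted p = 3.4e-05, adjusted p = 0.30 with an estimated correlation). In the unfolded protein and integrated stress response 19 genes were higher and 1 lower of 22 (median 1.51, adjusted p = 2.7e-10, adjusted p = 0.31 with an estimated correlation). Ribosome biogenesis, with 15 of 20 genes higher, kept its call with either correlation (adjusted p = 2.1e-07, adjusted p = 0.048 with an estimated correlation), but lost it when the replicate block was added to the latter (0.15), an alternative chosen after seeing the data. Without PE, 30 of 30 cell cycle genes (median -1.60, adjusted p = 1.6e-18, adjusted p = 0.33 with an estimated correlation) and 14 of 20 extracellular matrix genes (16 adjusted over the list alone; median -0.89, adjusted p = 0.00014, adjusted p = 0.43 with an estimated correlation) were lower at 50 µM. Beside the matrix genes, 4 of 11 fibroblast markers were lower, 8 with the replicate block (median -0.65, adjusted p = 0.031, adjusted p = 0.49 with an estimated correlation). So were 7 of 11 smooth muscle markers (8 adjusted over the list alone; median -0.78, adjusted p = 0.023, adjusted p = 0.56 with an estimated correlation). With PE, 4 of 11 smooth muscle markers were lower at 50 µM, 10 with the replicate block and 2 after quantile normalization (3 adjusted over the list alone; median -0.58, adjusted p = 0.026, adjusted p = 0.68 with an estimated correlation). limma called 4320 genes between doses with PE (2231 higher, 2089 lower) and 5276 without (2663 higher, 2613 lower).

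The PE response was then measured inside each dose, to see whether the inhibitor changed it. At 10 µM, PE still raised Acta1 (2.25, adjusted p = 5.6e-07) and Nppb (1.68, adjusted p = 0.0011), and each of 24 genes of sterol and fatty acid synthesis rose (median 1.46, adjusted p = 4.7e-17, adjusted p = 0.52 with an estimated correlation). Fibroblast markers and extracellular matrix genes were lower with PE at 10 µM (camera adjusted p = 0.0061 and 0.0011). Neither list passed with the replicate block and an estimated correlation, chosen after seeing the data (0.44 each). At 50 µM, PE left Acta1 at 0.02 (adjusted p = 0.96), while Ankrd1 rose by 0.83 (adjusted p = 0.0044, and 0.052 in a fit of the compared groups only) and Nppb by 1.32 (adjusted p = 0.013, and 0.0509 without 50 µM replicate 3). Sterol and fatty acid synthesis still rose at 50 µM, in 21 of 24 genes (22 adjusted over the list alone; median 1.06, adjusted p = 6.1e-18, adjusted p = 0.30 with an estimated correlation). So did 20 of 30 cell cycle genes (25 adjusted over the list alone; median 0.85, adjusted p = 5.1e-17, adjusted p = 0.30 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose by 1.64 ± 0.14 (adjusted p = 2.6e-06). Of 28 genes of fatty acid oxidation 15 fell with PE at 50 µM (1 rose and 17 fell adjusted over the list alone; median -0.43, adjusted p = 3e-10, adjusted p = 0.30 with an estimated correlation). limma called 3408 genes at 10 µM (1979 higher, 1429 lower) and 1500 at 50 µM (975 higher, 525 lower), with 65% higher at 50 µM and 52.5% after quantile normalization. The count of 1500 was 945 without PE with 50 µM replicate 1, 2491 with the replicate block and 720 in a fit of the compared groups only.

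The difference between PE responses was tested as an interaction. On the log2 scale used, a negative value means a smaller fold rise or a larger fold fall with PE. It can come from a higher level with the inhibitor alone, and need not mean a lower level in PE with the inhibitor. At 10 µM the inhibitor raised Acta1 by 2.66 without PE and by 0.82 with PE. At 50 µM it changed Acta1 by 3.02 without PE and by -1.05 with PE. At 50 µM the interaction was -4.07 for Acta1, -3.79 for Tceal7 and -2.24 for Xirp2. It was -2.05 for Nppb (adjusted p = 0.014, and -1.45 with 0.0602 after quantile normalization), while Nppa did not pass (-1.76, adjusted p = 0.11), though it did with the replicate block (0.0253) and without Vehicle replicate 1 (-2.37, 0.014). Of 29 genes of oxidative phosphorylation 17 had a lower response, 28 with the replicate block (28 adjusted over the list alone; median -0.66, adjusted p = 2e-19, adjusted p = 0.38 with an estimated correlation). The complex I subunit Ndufs1 had a difference of -1.01 ± 0.18 (adjusted p = 0.0042). Of 15 genes of the tricarboxylic acid cycle 7 had a lower response, 15 with the replicate block (14 adjusted over the list alone; median -0.59, adjusted p = 4.8e-11, adjusted p = 0.38 with an estimated correlation). Of 28 genes of fatty acid oxidation 7 had a lower response, with 13 lower and 1 higher under the replicate block (9 adjusted over the list alone; adjusted p = 7.4e-08, adjusted p = 0.38 with an estimated correlation). Of 19 sarcomere genes 8 had a lower response (1 higher and 14 lower adjusted over the list alone; median -0.76, adjusted p = 3.6e-08, adjusted p = 0.38 with an estimated correlation); after quantile normalization 3 were lower and 1 higher, the median was -0.06 and the adjusted p 0.071. The quantile medians of oxidative phosphorylation and of the tricarboxylic acid cycle were -0.38 and -0.35. The myosin light chain Myl3 (-1.67 ± 0.20, adjusted p = 0.0002) and the LIM protein Fhl1 (-2.01 ± 0.20, adjusted p = 3.3e-05) were among the genes with a lower response. At 10 µM the difference was -1.31 ± 0.20 for Fhl1 (adjusted p = 0.0067) and -1.84 for Acta1. Among the 15 fetal and hypertrophic genes 4 had a lower response, 7 with the replicate block (8 adjusted over the list alone; median -0.92, adjusted p = 1.1e-11, adjusted p = 0.10 with an estimated correlation). The fetal list was not alone in passing camera with the preset correlation at 10 µM. Oxidative phosphorylation, the tricarboxylic acid cycle, the sarcomere, the cell cycle and immediate early genes were among others that did. With an estimated correlation these did not pass (camera adjusted p from 0.28 to 0.66). At 50 µM the fetal and cell cycle lists also passed with the preset correlation only (0.38 and 0.67 with an estimated one).

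Across genes, the PE response with the inhibitor had a slope of 0.94 on the response without it at 10 µM and 0.48 at 50 µM, corrected for noise; by replicate number the slopes were 0.854 ± 0.073 and 0.442 ± 0.107 (mean ± SD, n = 3). The noise was that of the fit without a block, so with paired libraries the correction may be too large. The 0.94 lay above the highest slope by replicate number, 0.906. Without 10 µM replicates 1 and 3 the slope of 0.94 was 1.022 and 0.858. limma called 734 genes at 50 µM (235 higher, 499 lower) and 32 at 10 µM (7 higher, 25 lower), with 2300 and 1018 at an unadjusted p under 0.05. The 734 became 480 and 392 without Vehicle replicates 2 and 3, 400 and 450 without PE replicates 1 and 2, 428 and 477 without PE with 50 µM replicates 1 and 3, 448 without 50 µM replicate 2, and 1690 with the replicate block. The 32 became 15 and 19 without Vehicle replicates 2 and 3, 14 and 16 without PE replicates 2 and 3, 13 without PE with 10 µM replicate 1, 13 without 10 µM replicate 2, and 230 with the replicate block.

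**Figure D3:**
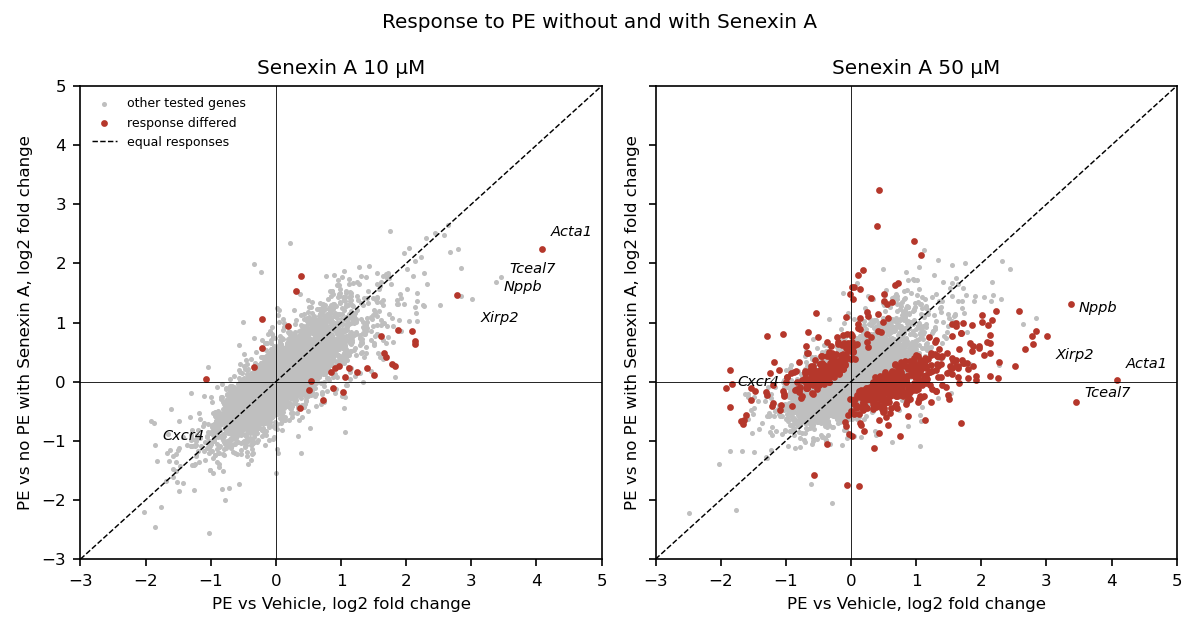
Log2 fold change of PE against no PE with Senexin A at 10 µM (left) or 50 µM (right), against that of PE without the inhibitor; each point is a gene, red where the responses differed (32 and 734 genes), and the dashed line marks equal responses. Acta1 has 4.09 without the inhibitor and 0.02 at 50 µM.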

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

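The tests of a scaled-up response, of a loss of other cells, of scaling on the gene lists and of a ceiling on the genes lowered in PE, and the reading of the splits by inhibitor and PE, were chosen only after the result was seen; the ceiling on the other genes was added later too, before its value was known, and the remaining tests were planned.

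Each result in this paragraph stands here because the responses to PE differed on the log2 scale by the interaction test. At 10 µM 32 genes differed and at 50 µM 734 did (limma, adjusted p under 0.05). At 10 µM the difference was 1.39 for Neil2, 1.26 for Nrbp2, 1.23 for Ebp, 1.11 for Ptgds, 0.79 for Glrx and 0.76 for Rbmx2. It was -1.84 for Acta1, -1.57 for S1pr1, -1.49 for Adamts19, -1.48 for Azin2, -1.43 for Csrp3, -1.41 for Fbxl22 and -1.27 for Ankrd1. Nrbp2, Ptgds, Acta1, Adamts19 and Fbxl22 passed without any 1 of the 12 libraries, though Adamts19 did not with a pseudocount of 0.1 (adjusted p = 0.155). Azin2 did not pass without PE replicate 2 or without PE with 10 µM replicate 1 (highest adjusted p 0.0615). Those omissions also ended the calls of Neil2, Ankrd1 and Csrp3, which were lost in 9 omissions each, Ebp and Glrx in 10, and Rbmx2 and S1pr1 in 11, with highest adjusted p-values of 0.146, 0.137, 0.132, 0.137, 0.143, 0.143 and 0.146. With no filter on low values the calls of Neil2, Ebp, Glrx, Rbmx2, S1pr1, Csrp3 and Ankrd1 were lost as well (adjusted p from 0.0728 to 0.103). A pseudocount of 0.1 ended those of Neil2 (0.264), Ebp (0.0541), Glrx (0.0605) and S1pr1 (0.0547), a fit of the compared groups only those of Csrp3 and Rbmx2 (0.0851 each), and quantile normalization those of Glrx (0.0556) and Ankrd1 (0.0545).

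At 50 µM the difference was 2.81 for Nap1l5, whose locus another gene shares, 2.24 for Neil2, 2.07 for Cxcr4, 2.06 for Abcg1, 1.81 for Atp6ap1l and 1.79 for Map2k6. It was -4.07 for Acta1, -3.79 for Tceal7, -2.4 for Bex1, -2.25 for Yipf7, -2.24 for Xirp2, -2.2 for Tppp, -2.05 for Nppb and -0.86 for Ankrd1. Cxcr4 did not pass without Vehicle replicate 3 (adjusted p = 0.0541) or 50 µM replicate 3 (0.0505). Ankrd1 lost its call in 8 omissions (Vehicle replicates 2 and 3, PE replicates 1, 2 and 3, PE with 50 µM replicates 1 and 3, 50 µM replicate 2; highest adjusted p 0.114). It also lost it after quantile normalization, where its value was -0.18 (adjusted p = 0.66), with no filter (0.1) and in the compared groups only (0.0589). Nppb did not pass after quantile normalization (-1.45, adjusted p = 0.0602).

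Most genes of the unfolded protein and integrated stress response were higher at 50 µM in both backgrounds. Of 22, 18 were higher and 3 lower without PE, and 19 and 2 with PE. The list passed camera in both, but not with an estimated correlation (adjusted p = 0.54 and 0.53). If 50 µM acted as a scaled-up 10 µM, the list median at 10 µM without PE would be 0.42, but it was 0.02 ± 0.08 (SD over 3 replicate numbers), a difference of -0.4 that argues against this. With PE the values were 0.59 and 0.24 ± 0.17, and the difference of -0.35 (SD 0.2) is too variable, so a scaled-up response cannot be told apart from another there. Scaling between libraries is argued against, since 17 of 18 raised members without PE and 18 of 19 with PE kept their calls after quantile normalization. An effect that sets in between the doses may underlie the pattern, and whether it runs through CDK8 or through another target at 50 µM was not tested.

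Cell cycle genes were lower at 50 µM in both backgrounds. The median of the 8 macrophage markers did not fall at 50 µM, at 0.06 ± 0.2 without PE and 0.48 ± 0.45 with PE. At 10 µM it was 0.58 ± 0.41 and 0.49 ± 0.15, so without PE it stood lower at 50 µM than at 10 µM. With that drop and this spread, the macrophage markers do not decide whether non-muscle cells of every type were lost. The other marker lists fell in both backgrounds. Without and with PE, fibroblast markers stood at -0.54 ± 0.38 and -0.48 ± 0.07, and endothelial ones at -0.47 ± 0.06 and -0.48 ± 0.05. Smooth muscle markers stood at -0.63 ± 0.35 and -0.31 ± 0.03, and epicardial ones at -0.49 ± 0.22 and -0.43 ± 0.35. The list that fell furthest lay above the cell cycle median by 1.21 without PE and 1.07 with PE. Changes of low genes are understated on this scale, so a loss of these cell types stays open. Without PE a scaled-up 10 µM response remains open, with a difference of 0.19 between the median of -0.30 ± 0.26 and the -0.48 it predicts, while with PE the difference was 0.45 (-0.04 ± 0.15 against -0.49). Scaling is argued against by 30 of 30 calls kept in each background. Less division, or fewer dividing cells of a type that outlasted the 48 h of AraC given to every library against such cells, may account for it, and neither was tested.

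Of the 1874 genes that rose with PE, 448 (23.9%) rose less at 50 µM by the interaction on the log2 scale, and 17 rose more. Choosing genes by PE against Vehicle favours smaller responses, so the reverse choice, by PE at 50 µM, was read beside it. Of 975 genes raised there, 48 had a smaller response than without the inhibitor and 94 a larger one. Of 525 lowered there, 8 had a smaller response and 62 a larger one. As for a ceiling that PE already reaches, 217 of the 448 lay lower in PE with 50 µM than in PE. The 448 were chosen with the same PE libraries, which favours such a fall, so that count does not decide. Among the 231 others 86 lay higher, which argues against a ceiling for those genes. The rest of the 231 were called neither way there, so a ceiling stays open for them. Choosing genes by their PE response would give near 50% smaller responses among all 734 genes, and 78.7% were smaller (75% to 83.4% with single libraries left out). Scaling is argued against for 376 of the 448 (83.9%), which kept their calls after quantile normalization. It stays open for the rest, among them Actc1 (-0.31, limma adjusted p = 0.365), Ankrd1 (-0.18, 0.66) and Nppb (-1.45, 0.0602). The sarcomere, glycolysis and heat shock lists also lost their interaction calls after quantile normalization (camera adjusted p = 0.071, 0.067 and 0.78). Of the 448, 231 were only raised by the inhibitor without PE, 162 only lowered by it in PE, and 55 both (adjusted p under 0.05). A gene short of that threshold may have moved too, and no biological explanation was tested. The Vehicle libraries were also used to choose the 448, which favours a rise without PE. The interaction is the difference of these 2 inhibitor effects, so a gene called in it is likely to be called in 1 of them. Of the 448, 0 were called in neither, so this division comes in part from the choice. The 448 became 237 without Vehicle replicate 3, 250 and 285 without PE replicates 1 and 2, 282 and 288 without PE with 50 µM replicates 1 and 3, and 273 without 50 µM replicate 2, but 887 with the replicate block; of the 1331 genes that fell with PE, 143 fell less (402 with the block, 252 after quantile normalization, and 66 to 90 without Vehicle replicate 2 or 3, PE replicate 1 or 2, PE with 50 µM replicate 1 or 50 µM replicate 2).

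For the 9 comparisons of 2 groups the splits of 6 libraries are too few, 10 each, for a share under 0.05, and in each only 1 split, the real one, gave as many genes. The real counts were 3205, 1778, 5939, 1696, 6361, 3408, 1500, 4320 and 5276, and the highest of the other splits were 1, 0, 0, 0, 1, 0, 2, 0 and 0, in the order PE, 10 and 50 µM with PE, 10 and 50 µM without PE, PE with 10 and 50 µM, and 50 against 10 µM with and without PE. Other splits that part all replicate numbers called 0 genes by limma.

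For the interactions chance could not be excluded by splits. At 10 µM 7 of 100 splits called as many as the real 32 (highest other 2377), and at 50 µM 10 of 100 called as many as the real 734 (highest other 4211). Splits that call several times the real count point to a structure of the samples: the 6 and 9 others as large each had a net of at least 8 of the 12 libraries sorted by inhibitor or by PE (those on the matching side less those on the other), so that a main effect entered the interaction. The 82 others, whose net was 4 or less, called at most 10 and 87. With splits drawn within replicate numbers, as the real one is, 10 and 16 others were as large (highest 4491 and 6998), each with at least 8 by inhibitor or PE, and 75 others called at most 16 and 493.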

How the results depend on the processing

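The replicate block with an estimated correlation was chosen only after the data were seen; the other alternatives were planned, and in this part the cause of a change was not tested unless stated. With the replicate block limma called 2924 genes for 10 µM with PE, 2761 for 10 µM without PE, 2491 for PE at 50 µM, and 230 and 1690 for the interactions, with overlaps of 350 and 264 (higher and lower with PE, opposite at 10 µM) and 629 (lower with PE, higher at 50 µM). It also brought 15 results of named genes and 24 of lists past the threshold, and changed no other call. Array weights gave 86 and 1265 for the interactions, and no filter on low values gave 20 at 10 µM. A fit of the compared groups only, with fewer samples, gave 720 for PE at 50 µM. A minimum change of 2-fold leaves fewer genes by construction: 334 for PE, 129 and 1084 for 10 and 50 µM with PE, 125 and 1281 without PE, 363 and 188 for PE at 10 and 50 µM, 567 and 741 between doses with and without PE, and 19 and 164 for the interactions. Leaving out 1 library, with the fewer samples that brings, gave 2162 to 2846 for PE, 1042 to 1575 and 5247 to 5606 for 10 and 50 µM with PE, 948 to 1457 and 5738 to 6102 without PE, 2410 to 3175 and 945 to 1315 for PE at 10 and 50 µM, 13 to 34 and 392 to 921 for the interactions, slopes of 0.858 to 1.022 and 0.431 to 0.527, and overlaps of 129 to 191, 84 to 105, 562 to 688 and 272 to 397 (higher with PE and lower at 10 µM, lower and higher at 10 µM, and the same at 50 µM). The libraries that moved these by over 1.5 times are named beside the counts they moved. Actc1 reversed, from 0.87 for PE at 10 µM to -0.48 after quantile normalization (adjusted p = 0.0124). Of 1193 results of named genes, quantile normalization ended 69 calls, a pseudocount of 0.1 ended 19 and 0.5 ended 7, median-ratio scaling ended 9, no filter ended 87 and the compared groups only ended 103. Of the 119 list calls, 118 were lost with an estimated correlation and 17 after quantile normalization, and 0 held with the replicate block and an estimated correlation (limma's camera). Absolute depth is unknown, so a gene at the floor of 0.01 FPKM is not shown to be absent.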

Other observations

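None of the values here comes from a test chosen after the result was seen, except the deviations by replicate number, which were computed after the pairing was, and the replicate block with an estimated correlation. Lists of other stress defences were tested at 50 µM, and no difference between their responses with and without PE passed in camera (interaction adjusted p = 0.63 for oxidative stress, 0.081 for p53 targets and 0.42 for autophagy), though that of the p53 targets did in fry (0.016). With PE, 9 of 15 genes of the oxidative stress response rose and 3 fell (9 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 0.044, adjusted p = 0.71 with an estimated correlation, and 0.088 after quantile normalization), among them the metallothioneins Mt2A (3.00 ± 0.29, limma adjusted p = 3.8e-07) and Mt1a (2.94 ± 0.33) and the heme oxygenase Hmox1 (1.81). Without PE 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.074, 0.04 with the replicate block, and 0.49 with the block and an estimated correlation). Of 14 p53 targets 8 rose and 2 fell at 50 µM in each background (4 fell with PE under the replicate block), with Gdf15, a secreted stress cytokine, higher by 2.08 ± 0.21 with PE (adjusted p = 7.5e-07) and by 2.54 ± 0.21 without (adjusted p = 8.1e-08). The list had adjusted p = 0.21 with PE and 0.046 without (adjusted p = 0.40 with an estimated correlation, and 0.078 after quantile normalization). Of 17 genes of autophagy and protein degradation 10 rose and 1 fell at 50 µM without PE (adjusted p = 0.031, adjusted p = 0.54 with an estimated correlation, and 0.13 after quantile normalization), among them Sqstm1, an autophagy receptor (1.44 ± 0.14). With PE 7 rose and 1 fell (adjusted p = 0.12).

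Of 21 interferon response genes 10 fell at 50 µM with PE, 13 with the replicate block (10 adjusted over the list alone; median -0.56, adjusted p = 0.016, adjusted p = 0.53 with an estimated correlation) and 10 without PE, 15 with the replicate block (8 adjusted over the list alone; median -0.61, adjusted p = 0.018, adjusted p = 0.54 with an estimated correlation, and 0.074 after quantile normalization). At 10 µM 2 fell with PE, 6 with the replicate block (median -0.21, adjusted p = 0.026, adjusted p = 0.85 with an estimated correlation, and 0.061 after quantile normalization) and 2 without, 6 with the replicate block (1 adjusted over the list alone; median -0.28, adjusted p = 0.015, adjusted p = 0.59 with an estimated correlation). With PE, Ifit1, an antiviral RNA-binding protein, fell by 1.41 ± 0.18 at 10 µM (adjusted p = 0.00014) and by 1.89 ± 0.18 at 50 µM (adjusted p = 3.4e-07). Of 22 genes of adrenergic and Gq signalling 7 rose at 10 µM without PE (8 adjusted over the list alone; median 0.24, adjusted p = 0.0028, adjusted p = 0.37 with an estimated correlation), and 5 rose and 7 fell at 50 µM (adjusted p = 0.6). With PE, 8 rose and 4 fell at 50 µM (median 0.20, adjusted p = 0.61). Of the same 22, 11 were lower and 3 higher at 50 µM than at 10 µM without PE (12 and 3 adjusted over the list alone; median -0.62, adjusted p = 0.023, adjusted p = 0.35 with an estimated correlation), among them the endothelin receptor Ednra (-1.95 ± 0.12). Of 25 genes of core Mediator, the complex that CDK8 joins, 9 rose and 3 fell at 50 µM with PE (median 0.14, adjusted p = 0.33), with Med9 higher by 0.83 ± 0.12 (adjusted p = 2.2e-05) and Med20 by 0.45 ± 0.07 (adjusted p = 4.8e-05).

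Marker lists of other cells also followed the replicate numbers. The mean deviation of atrial markers from the group means over the 6 groups was 0.63 ± 0.04 (SD) in replicate 1, above in 6 of 6 groups, and -0.67 ± 0.06 in replicate 3. For macrophage markers it was 0.70 ± 0.23 in replicate 2 and -0.67 ± 0.16 in replicate 3, and for fibroblast markers 0.34 ± 0.18 in replicate 3 and -0.22 ± 0.06 in replicate 2. Smooth muscle markers stood at 0.29 ± 0.12 in replicate 1 and -0.31 ± 0.05 in replicate 2.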
